A study of Mus musculus with 81 samples.

How the data were processed

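Gene expression was measured by RNA sequencing in a mouse hybridoma mature T cell line. Of the 65 columns of the count table, 41 hold libraries that could be matched to a labelled sample, and 24 were not used here. Of the unused columns, 2 share 1 heading, so they could not be told apart, and the others name no sample of the series. The 41 libraries form 5 experiments. The first compares a control line with lines 2-12 and 2-14, which were depleted of RBPJ by CRISPR, with 2 libraries per line. The second follows a fusion of the Notch1 intracellular domain to the estrogen receptor (NICD1-ER) after 4-hydroxytamoxifen (4-OHT) at 1 µM for 4, 8 or 24 h, or after ethanol for 24 h, in 10 libraries. The third compares GFP with GFP-KYOT2 wild type and with GFP-KYOT2 WWAA, a mutant that does not bind RBPJ per the labels, with 3 libraries each. The fourth compares the gamma-secretase inhibitor DAPT (GSI, 20 µg/ml for 24 h) with DMSO, with 2 libraries each. The last compares biotin-tagged NICD1 (BioNICD1) with its control vector (Biocontrol) in control and in RBPJ-depleted cells, with 3 libraries for each of the 4 groups. Nothing in the labels says that replicates are separate cultures.

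The deposited table holds raw read counts per gene symbol, 24391 in all, as whole numbers with a different total in each library. Deposited lists give the start and end positions of regions, a unit of another kind than counts, for RBPJ in the control line and with BioNICD1, and for H3K27ac, H3K4me1, H3K4me3 and ATAC-seq. Their score column is 0 throughout, and how replicates were combined is not stated. The histone mark lists name no line; the series holds these marks in control cells and in line 2-12, so each list may pool both. The authors name TopHat2 2.1.1, Picard, deepTools and the mouse build mm9 without their roles, and no counting tool, annotation or peak caller. Other chromatin samples of the series were not used here.

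Library totals ran from 2377028 to 5998832 counts in the depletion experiment, where the control libraries held 2377028 and 4805039. They ran from 4325641 to 5395008 in the NICD1-ER experiment and from 9401514 to 14244209 in the KYOT2 experiment. They ran from 4992690 to 6327603 in the GSI experiment and from 8113019 to 10113741 in the BioNICD1 experiment. The ribosomal transcript Rn45s held 1.81 to 5.56% of the counts in the KYOT2 libraries and at most 0.263% elsewhere. The level that 3 counts represent in a library ran from 0.211 to 1.26 CPM (counts scaled to the library total). A ratio against a group at 0 counts was computed with the floor of 3 counts over the group and is a lower bound. A ratio against a group with 1 to 3 counts is given with its exact 95% counting interval. Intervals and floors cover counting error only.

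Each experiment was fitted alone in edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr and 1 mean per group. Contrasts were tested two-sided with quasi-likelihood F-tests, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are on the log2 scale with their standard error (SE), and group means are TMM-normalised CPM with their standard deviation (SD). The prior count was 0.125. The effect of both edited lines is the mean of lines 2-12 and 2-14 minus the control. At 4 and 8 h, 4-OHT was compared with ethanol at 24 h, since no earlier ethanol group exists. The BioNICD1 contrasts in control and in depleted cells, their interaction and the depletion contrast share libraries and therefore chance values.

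Pairs of libraries were checked against sampling noise by the chi-square per gene over genes with at least 50 counts. NICD1-ER replicates 1 and 2 differed by less than sampling noise at 4 h (0.914) and at 8 h (0.849), while the other pairs of those groups differed by more. Each such pair was summed and counted as 1 sample, which leaves 2 samples per NICD1-ER group; this replaced the planned use of each library as a sample. The pair at 24 h of 4-OHT (0.939) and the GSI pair (0.767) also fell below 1, but each is the only pair of its group, so they were kept apart. Their errors may understate the spread between cultures.

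Replicate numbers were checked for pairing by the correlation of residuals across genes. In the depletion experiment libraries with the same number correlated at r = 0.433 to 0.608, and 6 of 6 libraries correlated best with one of their own number. With 2 libraries per group these correlations take only 3 distinct values. Fits with the replicate number as a block are therefore given beside the counts of that experiment. In the KYOT2 experiment 8 of 9 libraries correlated best with one of their own number. Same-number r there was 0.0349 to 0.408, against −0.285 to 0.161 for other pairs. Counts with the block are therefore given for KYOT2 too. The labels name no shared culture, day or batch, so the main fits hold no block.

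Before the data were examined, the comparisons, tests, alternatives, gene lists and the rule for named genes were fixed. The rule takes, in each main comparison, the 8 largest increases and 8 largest decreases among genes that passed the test, had a mean of at least 5 CPM and did not overlap between groups (3 of each in the other comparisons), together with 13 fixed genes of the Notch pathway and 4 members of each list that was called. Single genes that the rule selects are in part not reported here. The lists are Notch targets, Notch pathway machinery, RBPJ cofactors, T cell identity, T cell activation, proliferation, MYC and ribosome biogenesis, glycolysis and hypoxia, interferon response, p53 targets, ER stress and ATF4, cholesterol synthesis, and markers of B cells, myeloid cells, erythroid cells and fibroblasts. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1), beside camera with an estimated correlation, and their members were also adjusted over the list alone. Genes called in 1 experiment were tested as a set in another with fry, beside camera at the preset correlation, and overlaps of calls with Fisher's exact test, two-sided, adjusted over 20 overlaps.

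Region lists were compared by overlap of at least 1 bp, with exact 95% binomial intervals, beside 100 seeded random placements within the span that the lists cover, which were also judged by the 2 stricter overlap rules after a look at the data (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9). No annotation of mm9 was used here, so regions were not assigned to genes.

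The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, the replicate block, leaving out each library, 1 fit over all libraries, lists of genes changed at least 2-fold, overlap of at least 50% of a region and the midpoint of a region. Leaving out a sample of a group of 2 leaves 1 sample there, and the error then comes from the other groups only. No count of genes is given for such a fit. Whether a single gene passed in it is no measure of the spread within that group. After seeing the data, the near-identical libraries were also kept apart (with and without the block), the pairs at 24 h of 4-OHT and of GSI were summed, the 2 most distant depleted BioNICD1 libraries were left out, and lists were tested without the targeted or expressed gene. The tests were tested on simulated data made from these counts. For a 2-fold change edgeR called 68% of 50 changed genes in the depletion design, 84% in the NICD1-ER design, 92% in the KYOT2 and GSI designs and 84% for BioNICD1 in control cells. False calls made up 5.84% of all calls in the depletion design and 28.2% of them without the low-count filter. With DESeq2 they made up 13.5% in the depletion design and 12.4% for BioNICD1 in control cells. They made up 1.69% in the NICD1-ER design and 4.40% in the KYOT2 design. Simulated libraries were drawn independently, so these rates leave out the correlation between replicates of the same number.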

Results

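Expression was measured in 41 libraries from 5 experiments, with 2 or 3 samples per group and 24391 gene symbols. Depth, filters and tests are given with the processing of the data. A ratio given as "at least" compares with a group without counts, and a ratio with a range compares with a group that holds 1 to 3 counts; both cover counting error only. Fitted log2 fold changes of such genes depend on the prior count and are no bound.

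Rbpj, the targeted gene, was at 157 ± 34.4 CPM (mean ± SD, n = 2) in the control line, at 37.8 ± 9.02 CPM in line 2-12 (n = 2) and at 50.7 ± 12.6 CPM in line 2-14 (n = 2). In the BioNICD1 experiment Rbpj was at 90.9 ± 2.86 CPM in control cells with Biocontrol and at 85.8 ± 2.63 CPM with BioNICD1 (n = 3 each). Depleted cells there held 19.3 ± 0.607 CPM of Rbpj with Biocontrol and 24.4 ± 2.62 CPM with BioNICD1 (n = 3 each). With NICD1-ER, Rbpj was at 210 ± 4.73 CPM in ethanol and at 163 ± 4.52, 158 ± 0.758 and 157 ± 0.571 CPM after 4, 8 and 24 h of 4-OHT (n = 2 each). Rbpj was at 141 ± 1.43 CPM with GFP, 183 ± 6.35 CPM with KYOT2 wild type and 149 ± 13.0 CPM with KYOT2 WWAA (n = 3 each). With DMSO Rbpj was at 181 ± 6.10 CPM and with GSI at 209 ± 3.69 CPM (n = 2 each). Transcript remained in the depleted lines, and counts per gene do not show whether it encodes working protein.

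In the depleted lines the Notch target Hes1, a transcriptional repressor, rose from 1.00 ± 1.12 CPM in the control to 40.1 ± 21.8 CPM (log2 fold change 5.71, SE 1.04, adjusted p = 0.0222, edgeR, n = 4 and 2). Without control replicate 1 the value for Hes1 was 7.40 (adjusted p = 0.104) and without control replicate 2 it was 4.43 (adjusted p = 0.0921). Lgmn, which encodes the protease legumain, rose 57.3-fold (log2 5.83, SE 0.31, adjusted p = 0.000267). The receptor gene Notch1 rose from 6.95 ± 1.57 to 24.2 ± 2.73 CPM (log2 1.74, adjusted p = 0.00619). Rbpj fell by 1.85 log2 units (SE 0.211, adjusted p = 0.0043). Myc did not pass (0.05, adjusted p = 0.806).

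In the depleted lines the RING finger protein gene Lonrf3 rose from 1 count in the control to 117 ± 14.9 CPM (ratio 817, 146 to 32285). Ccdc91, a trafficking factor gene, rose 291-fold (log2 8.15, SE 0.247, adjusted p = 4.3e-05). Mina, a ribosomal oxygenase gene, rose at least 27.4-fold from 0 control counts. Tpd52, a vesicle protein gene, rose with a ratio of 384 (68.8 to 15181). Marveld1 rose at least 43.3-fold. Among decreases, Klhl6, a ubiquitin ligase adaptor gene, fell from 45.5 ± 12.3 CPM to 1 count (ratio 982, 175 to 38892). Crip1 was absent from the depleted lines and fell at least 139.9-fold, and the prostaglandin receptor gene Ptger3 fell at least 127-fold. The arrestin gene Arrdc4 fell from 51.0 ± 3.57 CPM (ratio 524, 144 to 4341). The lectin gene Clec2f fell with a ratio of 221 (74.6 to 1078).

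Of 11566 genes tested in both edited lines together, 718 rose and 426 fell, 1144 in all. DESeq2 called 1287 genes, and the fit with the replicate number as a block called 4260, of which 49.8% rose. Leaving out any of these libraries leaves 1 sample in its group. The error then comes from the other groups only, so no count of such a fit is given.

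Interferon response genes were higher in the depleted lines, with a median log2 fold change of 2.37 over 14 genes (camera adjusted p = 4.21e-12; adjusted p = 0.0742 with an estimated correlation). Of these 8 passed over all genes and 11 passed adjusted over the list alone, none of them down. Gbp2, an interferon-induced GTPase gene, rose 47.5-fold (log2 5.49), and Mx1, an antiviral GTPase gene, rose by 4.58 log2 units. Notch targets had a median of 1.11 over 11 genes (adjusted p = 3.17e-06; adjusted p = 0.213 with an estimated correlation), with 6 up and 1 down adjusted over the list alone. Cholesterol synthesis genes had a median of −0.45 over 16 genes (adjusted p = 5.95e-05; adjusted p = 0.803 with an estimated correlation), with 10 down adjusted over the list alone. Glycolysis genes had a median of −0.51 (adjusted p = 0.00108; adjusted p = 0.803 with an estimated correlation) and ER stress genes a median of −0.50 (adjusted p = 0.00473; adjusted p = 0.803 with an estimated correlation), with 0 members passing over all genes in each. With the replicate block the 4 named members of each list passed, Slc2a1, Pgam1, Eno1 and Adm (adjusted p = 0.00392 to 0.0105) and Hspa5, Atf4, Asns and Phgdh (adjusted p = 0.00357 to 0.0241), all downward, and with DESeq2 Slc2a1, Pgam1, Hspa5, Atf4 and Asns did.

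The other lists did not pass. Notch pathway machinery had a median of 0.15 (adjusted p = 0.577), RBPJ cofactors 0.01 (0.607), T cell identity 0.06 (0.453) and proliferation −0.18 (0.1003). T cell activation had a median of 0.36 and a mean of 0.34 while camera pointed down (0.606). Myeloid markers had a median of 2.80 over 3 genes, or 2.03 with ratios bounded at the floor (0.577). The MYC list had a median of 0.0066 and a mean of −0.03 (0.607), and p53 targets a median of −0.09 and a mean of 0.08 (0.607). Of the markers of other cells the highest in the depletion experiment were Cd22 of B cells at 4.94 CPM, Cd68 of myeloid cells at 31.7 CPM, Hba-a1 of erythroid cells at 5.18 CPM and Fn1 of fibroblasts at 0.179 CPM. Cd22 averaged 138 CPM over the NICD1-ER libraries. It passed upward both on depletion and with NICD1-ER at 24 h, so its level varied with condition and does not by itself point to B cells.

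In line 2-12 alone, Rbpj fell by 2.06 log2 units (adjusted p = 0.00767, n = 2 and 2), and Notch1 rose by 1.84. The receptor gene Il2ra rose there with a ratio of 77.2 (13.6 to 3078), adjusted p = 0.00831, and without control replicate 1 its value was 5.52 and did not pass. Line 2-12 had 559 genes up and 246 down, 805 in all, with 986 by DESeq2 and 3672 with the block. No count without a library is given, since 1 sample would be left in its group.

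In line 2-14 alone, Rbpj fell by 1.63 log2 units (adjusted p = 0.0177, n = 2 and 2). Without control replicate 1 the value was −1.40 (adjusted p = 0.0821) and without replicate 2 of line 2-14 it was −1.40 (adjusted p = 0.0868). Lonrf3 rose there with a ratio of 888 (159 to 35092). Line 2-14 had 393 genes up and 191 down, 584 in all, with 778 by DESeq2 and 3243 with the block. Counts without a library are not given here either, for the same reason.

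The lines differed from each other in Plekhg3, an exchange factor gene at 55.8 ± 5.13 CPM in line 2-12 (ratio 576, 103 to 22776, n = 2 and 2). The laminin gene Lamc1 was at 52.8 ± 6.79 CPM in line 2-14 (ratio 172, 58.7 to 839, adjusted p = 0.000543). Il2ra was at 10.5 ± 3.51 CPM in line 2-12 and 1.10 ± 0.519 CPM in line 2-14, which did not pass (log2 3.17, adjusted p = 0.0748). With the block the value for Il2ra was 3.20 (adjusted p = 0.00122) and DESeq2 gave 0.0231. Rbpj, Hes1, Notch1 and Myc did not pass between the lines. In all 35 genes were higher in line 2-12 and 21 in line 2-14, 56 together, with 118 by DESeq2 and 282 with the block. Leaving out a library of either line leaves 1 sample of it, so no count of that fit is given. Myeloid markers had a median of 0.88 (adjusted p = 0.00127; adjusted p = 0.379 with an estimated correlation) and proliferation genes −0.11 (adjusted p = 0.0491; adjusted p = 0.916 with an estimated correlation).

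**Figure D1:**
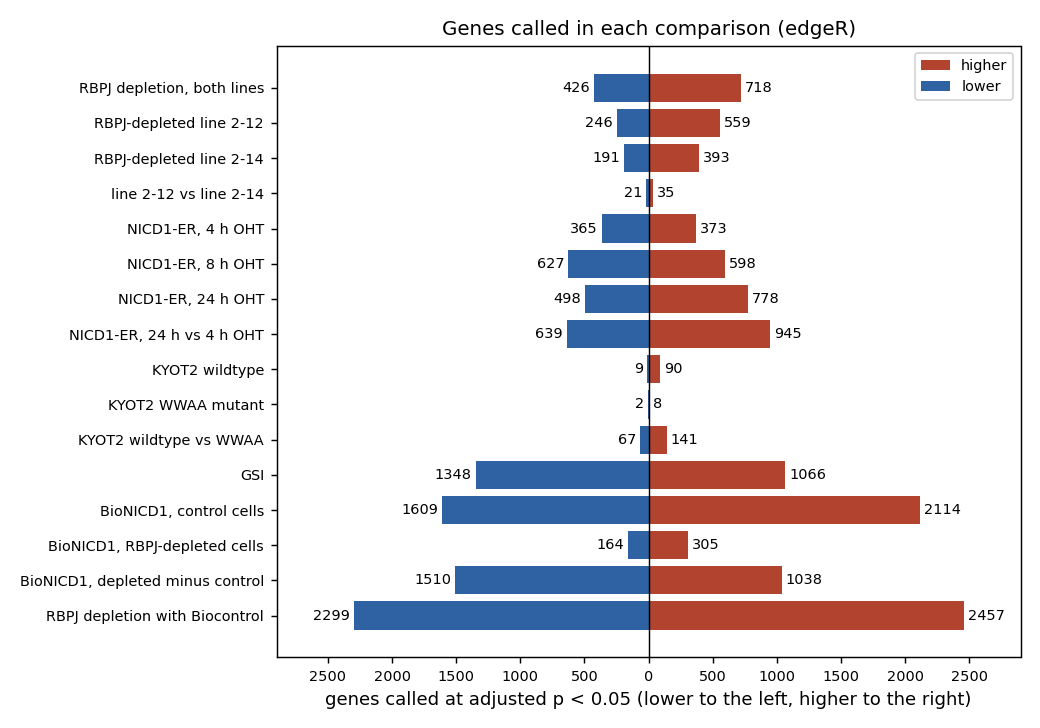
Genes that passed with edgeR in each comparison, higher to the right and lower to the left.

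**Figure D2:**
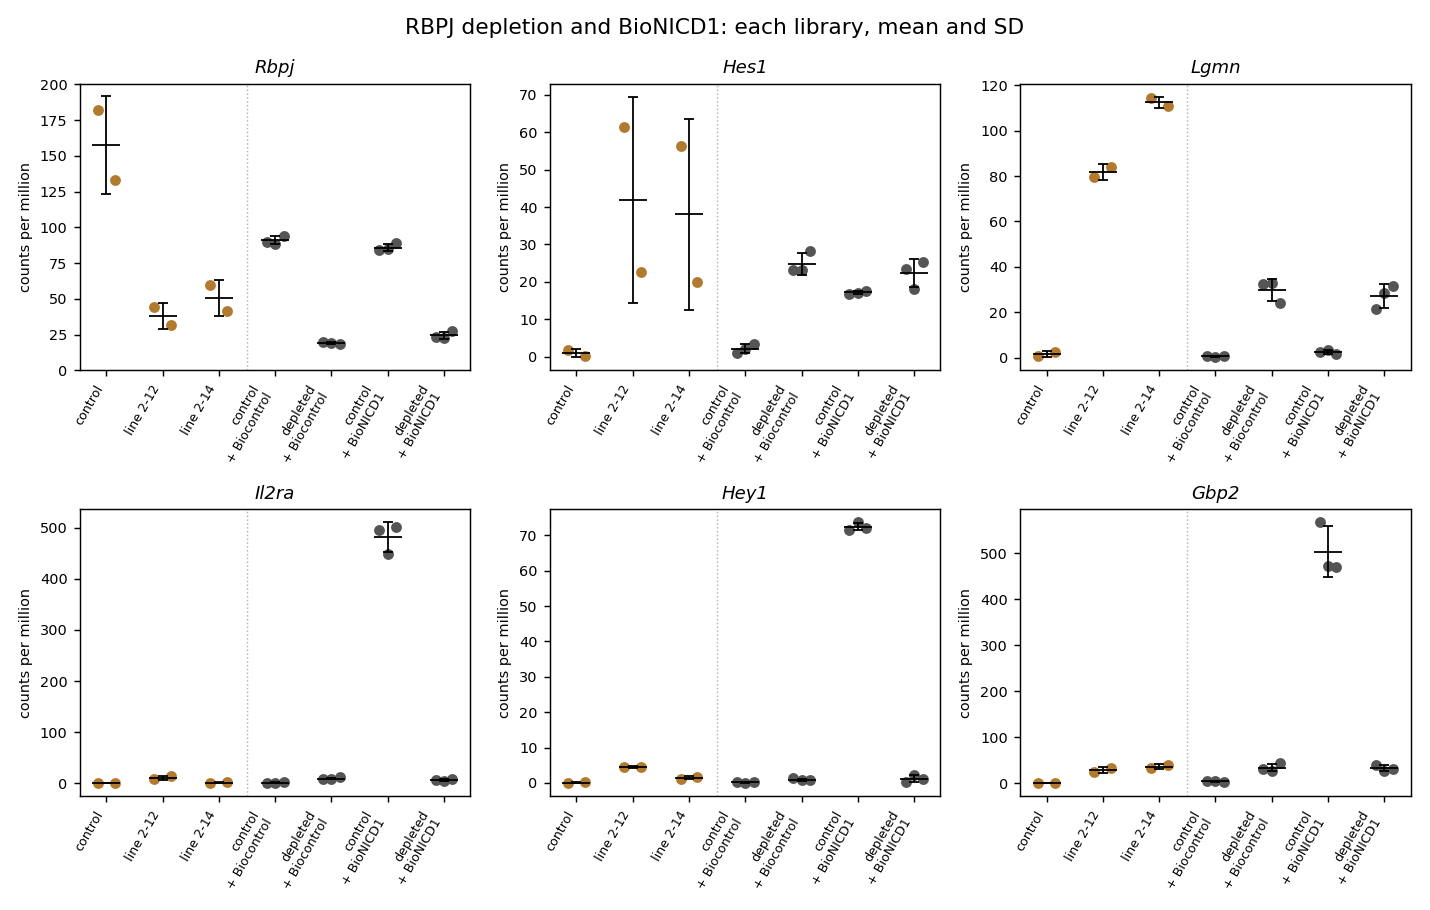
CPM of Rbpj, Hes1, Lgmn, Il2ra, Hey1 and Gbp2 in each library of the depletion and BioNICD1 experiments, with mean and SD.

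Depletion was also measured in cells with Biocontrol, where Hes1 rose from 2.22 ± 1.22 to 24.9 ± 2.97 CPM (log2 3.47, SE 0.261, adjusted p = 7.06e-07, n = 3 and 3). Lgmn rose 62.1-fold (log2 5.90) and Notch1 rose by 2.85 log2 units there. Il2ra rose 9.40-fold (log2 3.23) and Myc rose by 0.54. Rbpj fell by 2.24 log2 units (SE 0.0901, adjusted p = 4.69e-09). Hey1, another Notch target, did not pass (2.16, adjusted p = 0.0501). It passed with DESeq2 (2.23, adjusted p = 0.00697), with RLE factors (adjusted p = 0.0491) and without any of 3 libraries (adjusted p = 0.0085 to 0.0445). Ccdc91 rose from 0.203 to 293 ± 119 CPM, Mina rose at least 135-fold, and Lonrf3 rose 147-fold. The receptor gene Met fell at least 219-fold and Arrdc4 at least 157-fold. Gzmb, which encodes granzyme B, rose by 5.41 log2 units.

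With Biocontrol, depletion raised 2457 genes and lowered 2299, 4756 of 11315, with 4832 by DESeq2. T cell identity genes had a median of −0.05, with 4 up and 8 down of 23 (adjusted p = 0.104 with an estimated correlation). Among them the co-receptor gene Cd4 fell by 3.94 and Cd3d of the T cell receptor complex fell by 1.499. In the edited lines without Biocontrol, Cd4 went the other way and rose by 5.75 (adjusted p = 0.000132), and Cd3d did not pass (−0.15, adjusted p = 0.497). T cell activation genes had a median of 0.75 over 18 genes (adjusted p = 0.0451 with an estimated correlation) and Notch targets a median of 1.35 over 10 genes (adjusted p = 0.0451 with an estimated correlation). Of the Notch targets 5 rose and 3 fell, Dtx1 by 1.27 (adjusted p = 0.0183), the cyclin gene Ccnd1 by 0.86 and the transcription factor gene Tcf7 by 0.30. Dtx1 did not pass without replicate 1 of control cells with Biocontrol (−0.91, adjusted p = 0.0986) or replicate 2 of depleted cells with Biocontrol (−0.92, adjusted p = 0.0844). Without the low-count filter the median of Notch targets was 0.0579 and the list did not pass (adjusted p = 0.157). Interferon genes had a median of 0.78 over 17 genes (adjusted p = 0.0616 with an estimated correlation), with Mx1 up by 5.33.

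Genes that rose in the edited lines had a median log2 fold change of 0.62 in the Biocontrol depletion, where 80.9% of 690 were above 0 (fry adjusted p = 1.497e-11). Of them 412 passed upward and 62 downward. Genes that fell in the edited lines had a median of −0.50 there (adjusted p = 1.73e-10), with 227 of 405 passing downward and 27 upward. The experiments share no libraries, but they may share the edited lines.

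After 24 h of 4-OHT in NICD1-ER cells, the Notch target Hey1 rose from 3.03 ± 0.0441 to 66.3 ± 5.59 CPM (log2 4.44, SE 0.166, adjusted p = 1.11e-11, n = 2 and 2). The 2 libraries at 24 h of 4-OHT differed by less than sampling noise, so errors against them may understate the spread between cultures. The ubiquitin ligase gene Dtx1 rose from 87.1 ± 2.00 to 227 ± 1.76 CPM (log2 1.38), and Hes1 rose by 0.71 (adjusted p = 3.37e-06). Nrarp, a feedback regulator of Notch, rose with a ratio of 74.4 (25.2 to 363). Il2ra rose by 0.51 and Notch1 by 0.32, where reads of the construct cannot be told from the endogenous gene. Myc fell by 0.33 (adjusted p = 0.000732) and Rbpj fell by 0.42 (SE 0.0481, adjusted p = 9.91e-06).

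The transporter gene Slc45a4 rose 150.2-fold at 24 h (log2 7.19), and Prf1, which encodes perforin, rose at least 50.0-fold. Mgst1, a glutathione transferase gene, rose at least 60.2-fold, Gcnt2 rose with a ratio of 218 (74.4 to 1061) and the cytokine gene Il10 with a ratio of 105 (18.4 to 4165). The guidance receptor gene Nrp2 fell 4.21-fold, and the chemokine receptor genes Cxcr3 and Ccr6 fell 3.48-fold and 2.78-fold. In all 778 genes rose and 498 fell, 1276 of 11808, with 617 by DESeq2. The count was 746 and 761 without replicates 2 and 3 of 4-OHT at 24 h.

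At 24 h Notch targets had a median of 0.63 over 13 genes (adjusted p = 3.97e-17; adjusted p = 0.0218 with an estimated correlation), with 8 up and 1 down adjusted over the list alone. T cell activation genes had a median of 0.32 (adjusted p = 0.00695; adjusted p = 0.166 with an estimated correlation), with 8 up and 2 down adjusted over the list alone. Interferon genes had a median of 0.37 (adjusted p = 0.000399; adjusted p = 0.166 with an estimated correlation), with 8 up and 2 down adjusted over the list alone. Among them the ubiquitin-like Isg15 rose by 1.54 and its protease Usp18 fell by 0.69. MYC and ribosome biogenesis genes had a median of −0.13 (adjusted p = 8.38e-05; adjusted p = 0.192 with an estimated correlation), with 15 of 20 down adjusted over the list alone.

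After 4 h, Hey1 was at 17.5 ± 0.894 CPM (log2 2.504, adjusted p = 1.1e-06, n = 2 and 2) and Dtx1 rose by 0.89. Notch1, with reads of the construct, passed downward at 4 h, but not with DESeq2 (−0.24, adjusted p = 0.238). Slc45a4 rose 15.9-fold. Nos2, a nitric oxide synthase gene, fell 5.04-fold. In all 373 genes rose and 365 fell, 738 together, with 229 by DESeq2. As at 24 h, no count is given without a sample, since 1 would be left in its group. Notch targets had a median of 0.34 (adjusted p = 1.8e-08; adjusted p = 0.118 with an estimated correlation) and glycolysis genes −0.14 (adjusted p = 4.7e-14; adjusted p = 0.358 with an estimated correlation).

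After 8 h, Hey1 was at 33.1 ± 2.32 CPM (log2 3.42, n = 2 and 2) and Nrarp rose with a ratio of 28.9 (9.68 to 142). Dtx1 rose by 1.15 and Hes1 by 0.60. At 8 h Notch1 also passed downward, but not with DESeq2 (−0.21, adjusted p = 0.262). Nrp2 fell 3.68-fold. In all 598 genes rose and 627 fell, 1225 together, with 429 by DESeq2. Again no count is given without a sample, since 1 would be left in its group. At 8 h Notch targets had a median of 0.38 (adjusted p = 1.41e-11; adjusted p = 0.0215 with an estimated correlation).

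Between 4 and 24 h of 4-OHT, Hey1 rose by 1.94 and Nrarp by 2.78 log2 units (n = 2 and 2). Prf1 rose with a ratio of 245 (43.4 to 9755) and the cadherin gene Cdh15 rose 44.4-fold. The transcription factor gene Fosb fell 4.399-fold. Hes1 did not pass between these times (0.07, adjusted p = 0.573), nor did Rbpj (−0.05, adjusted p = 0.558). In all 945 genes were higher at 24 h and 639 at 4 h, 1584 together, with 481 by DESeq2. Without a sample of either time 1 is left there, so no count of that fit is given.

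In control cells BioNICD1 raised Hey1 from 0.208 ± 0.189 to 72.5 ± 1.07 CPM (log2 8.39, SE 0.431, adjusted p = 1.8e-08, n = 3 and 3). Dtx1 rose 150.4-fold (log2 7.22) and Il2ra rose from 0.946 ± 0.632 to 482 ± 28.5 CPM (log2 8.99). Hes1 rose 7.72-fold (log2 2.94, adjusted p = 3.41e-06) and Myc by 0.73 (adjusted p = 0.000235). Notch1, whose reads include the construct, rose from 0.846 to 169 ± 4.70 CPM. Rbpj did not pass (−0.08, adjusted p = 0.459).

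With BioNICD1 in control cells the granzyme genes Gzmb and Gzma rose 124-fold and 197-fold, and Prf1 rose with a ratio of 1054 (360.5 to 5115). The immunity-related GTPase gene Iigp1 rose from 0.282 to 355 ± 28.2 CPM. Cdh15 rose at least 258-fold, and the defensin genes Defa2 and Defa20, which hold identical counts, at least 238-fold. Met fell at least 227-fold, the starch-binding gene Stbd1 17.0-fold and the chemokine receptor gene Ccr2 13.6-fold. In all 2114 genes rose and 1609 fell, 3723 of 11315, with 3893 by DESeq2. Without the 2 most distant depleted libraries, which enter here only through the error of the fit, the count was 5882.

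Interferon genes had a median of 3.24 with BioNICD1 in control cells, and 17 of 17 rose (adjusted p = 2.14e-05 with an estimated correlation). Gbp2 rose by 6.87 and Isg15 by 2.70. Notch targets had a median of 2.64, with 9 of 10 up (adjusted p = 2.14e-05 with an estimated correlation). T cell activation genes had a median of 0.60 (adjusted p = 0.00017 with an estimated correlation) and T cell identity genes a median of 0.35, with 14 up and 1 down (adjusted p = 0.0187 with an estimated correlation). Glycolysis genes had a median of 0.40 (adjusted p = 0.0257; adjusted p = 0.0645 with an estimated correlation) and proliferation genes 0.29 (adjusted p = 0.0354; adjusted p = 0.0732 with an estimated correlation). ER stress genes had a median of −0.35 (adjusted p = 0.0257; adjusted p = 0.205 with an estimated correlation), with the stress factor gene Ddit3 down by 2.40.

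In depleted cells BioNICD1 left the Notch targets Hes1 (−0.15, adjusted p = 0.663), Hey1 (0.42, 0.667), Dtx1 (−0.21, 0.811), Il2ra (−0.58, 0.228) and Myc (0.18, 0.362) without a passing change (n = 3 and 3). Notch1 with the construct rose from 6.18 ± 1.40 to 888 ± 80.5 CPM. Bcor, a corepressor gene, rose from 28.4 ± 3.32 to 72.5 ± 7.33 CPM, and Gimap7, a GTPase gene of lymphocytes, rose 2.38-fold. The lipocalin gene Lcn2 fell 3.72-fold and the actin-binding gene Avil fell 2.58-fold. Proliferation genes had a median of 0.56 (adjusted p = 6.83e-05 with an estimated correlation), with 18 of 20 up adjusted over the list alone, among them the kinase gene Aurkb by 0.77.

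BioNICD1 changed 305 genes up and 164 down in depleted cells, 469 in all, with 766 by DESeq2 and 1285 without the 2 most distant depleted libraries. The count was 165, 187 and 1224 without replicates 1, 2 and 3 of depleted cells with Biocontrol, and 287 without replicate 1 of depleted cells with BioNICD1. It was 310, 306 and 304 without replicates 1, 2 and 3 of control cells with Biocontrol. Notch targets had a median of −0.07 and a mean of 0.69, with camera pointing up (adjusted p = 3.29e-07), and Notch1 itself was the gene that passed. Without Notch1 the median of the list was −0.14 (adjusted p = 0.824). The MYC list had a median of 0.28 (adjusted p = 0.188 with an estimated correlation) and ER stress genes −0.32 (adjusted p = 0.286 with an estimated correlation).

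The response to BioNICD1 was smaller in depleted than in control cells for Hey1 (difference of log2 fold changes −7.97, SE 0.864), Dtx1 (−7.43), Il2ra (−9.57) and Hes1 (−3.10, adjusted p = 4.02e-05). It was also smaller for Gzmb (−7.46) and Gbp2 (−6.93). Hes1, Il2ra and Gzmb were already raised in depleted cells with Biocontrol, and that level enters their differences. The interferon, T cell activation and Notch target lists had positive medians on that depletion, which enter their list differences too. The response was higher in depleted cells for Bcor (2.70), the chemokine receptor gene Ccr9 (3.13) and the guidance receptor gene Nrp1 (2.62). Notch1 did not differ by a passing amount (−0.45, adjusted p = 0.277). Interferon genes had a median difference of −3.19 (adjusted p = 1.56e-05 with an estimated correlation) and Notch targets −1.60 (adjusted p = 0.000289 with an estimated correlation). Without Notch1, whose reads include the construct, the median difference of Notch targets was −2.48 (adjusted p = 0.000214 with an estimated correlation). T cell activation genes had a median difference of −0.82 (adjusted p = 0.000512 with an estimated correlation) and glycolysis genes −0.36 (adjusted p = 0.0340 with an estimated correlation).

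The response differed for 2548 genes, 1038 higher and 1510 lower in depleted cells, with 3046 by DESeq2 and 4665 without the 2 most distant depleted libraries. The count was 1629, 1676 and 4361 without replicates 1, 2 and 3 of depleted cells with Biocontrol. It was 1614 without replicate 2 of control cells with Biocontrol and 1662 without replicate 2 of control cells with BioNICD1. Because these contrasts share libraries, their values are not independent.

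Genes that rose with NICD1-ER at 24 h had a median of 0.56 with BioNICD1 in control cells, with 397 of 713 passing upward and 64 downward (fry adjusted p = 1.73e-10). In depleted cells their median was −0.09 (fry adjusted p = 0.00514), where camera did not pass (adjusted p = 0.0510). The median difference was −0.66 (fry adjusted p = 6.47e-09), and camera passed there too (adjusted p = 5.39e-27). Genes that fell with NICD1-ER at 24 h did not fall as a set with BioNICD1 in control cells, where their median was 0.16 (adjusted p = 0.000186). The 27 tested that fell at least 2-fold had a median of −0.07 there (fry adjusted p = 0.0046), so the direction depends on the cut. Camera passed neither for all genes that fell (adjusted p = 0.210) nor for these 27 (adjusted p = 0.332).

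**Figure D3:**
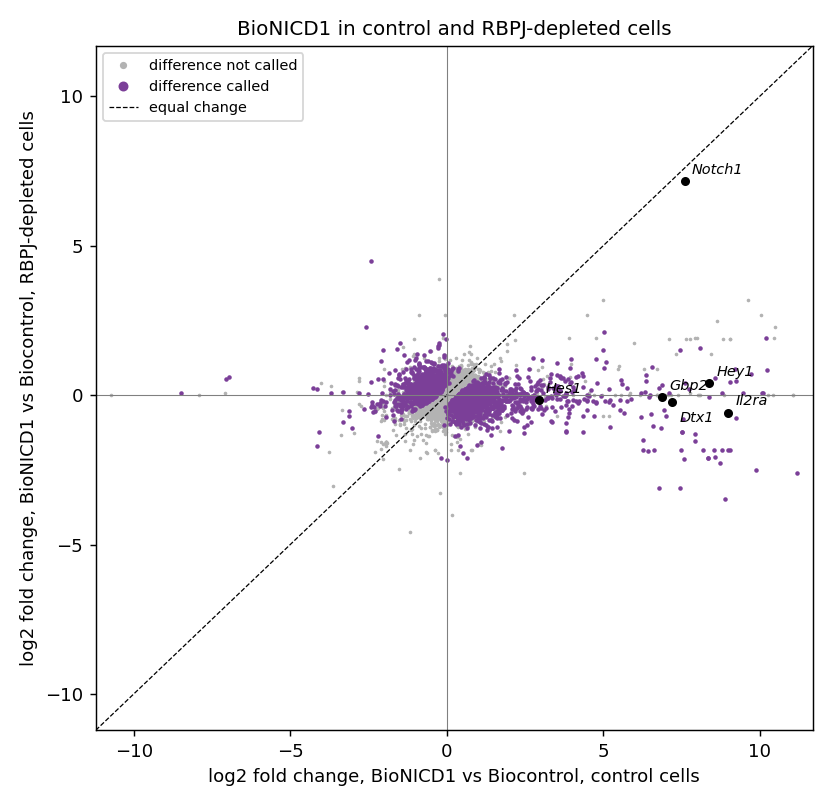
Log2 fold change with BioNICD1 in depleted cells against that in control cells, with genes whose response differed in purple.

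**Figure D4:**
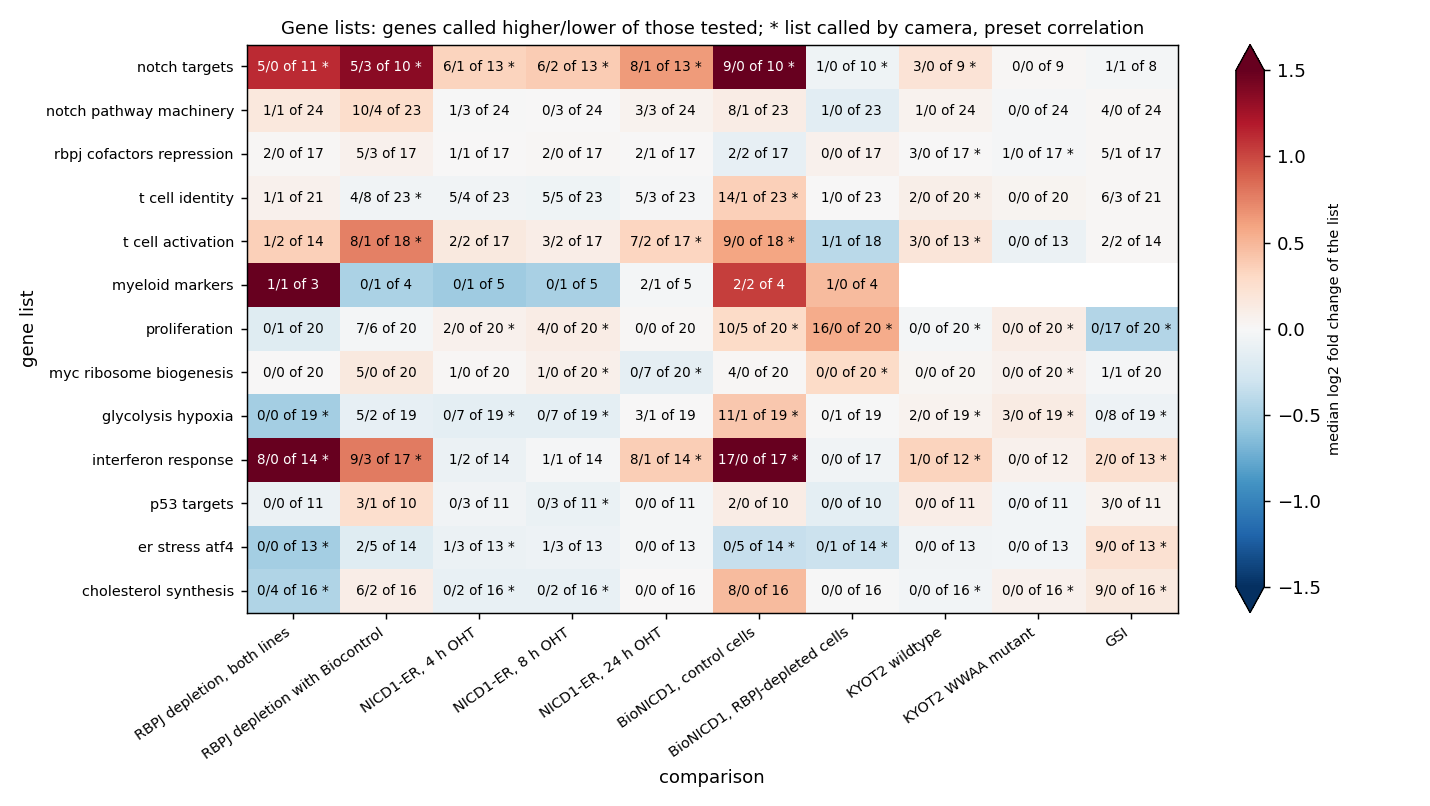
Median log2 fold change of each gene list, with the genes that passed upward and downward of those tested; an asterisk marks lists that passed with camera at the preset correlation.

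KYOT2 is a splice form of Fhl1, and Fhl1 was at 1093 ± 41.8 CPM with the wild type protein and 686 ± 27.3 CPM with WWAA, against 0.147 CPM with GFP (n = 3 each). With wild type, Lgmn rose from 0.370 ± 0.228 to 22.3 ± 1.18 CPM (log2 5.80, SE 0.219, adjusted p = 2.04e-09). Hes1 rose from 3.03 ± 0.645 to 9.12 ± 0.920 CPM (log2 1.59, SE 0.180, adjusted p = 0.000299) and Notch1 by 1.90. The lymphocyte GTPase genes Gimap8 and Gimap7 rose 8.57-fold and 7.48-fold. The costimulatory receptor gene Cd28 rose by 1.27 and Gzmb by 3.14. Rbpj rose by 0.38 (adjusted p = 0.00452), the RBPJ cofactor gene Spen by 0.46, and Avil fell by 0.49.

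With wild type KYOT2, 90 genes rose and 9 fell, 99 of 11150, with 105 by DESeq2. With the replicate number as a block 241 rose and 79 fell, 320 in all. The count was 55, 50 and 57 without GFP replicates 1, 2 and 3, and 63, 54 and 65 without those of wild type. It was 239 without WWAA replicate 3, which enters only through the error of the fit. Notch targets had a median of 0.21 (adjusted p = 0.00059 with an estimated correlation) and T cell activation genes 0.19 (adjusted p = 0.00449 with an estimated correlation). T cell identity genes had a median of 0.08 (adjusted p = 0.00813 with an estimated correlation) and interferon genes 0.33 (adjusted p = 0.0473 with an estimated correlation). RBPJ cofactors had a median of 0.01 (adjusted p = 0.00015 with an estimated correlation). Without Fhl1 the median was 0.0030 (camera adjusted p = 0.112 at the preset correlation and 0.211 with an estimated correlation).

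With WWAA, Hes1 (−0.83, adjusted p = 0.383), Notch1 (0.02, 0.997) and Rbpj (0.08, 0.746) did not pass (n = 3 and 3). The hypoxia gene Ankrd37 rose by 0.92 (adjusted p = 0.000811) and the hexokinase gene Hk2 by 0.50. In all 8 genes rose and 2 fell, 10 together, with 22 by DESeq2 and 67 with the block (45 up, 22 down). The count was 6 without GFP replicate 2 and 18 without WWAA replicate 3. Glycolysis and hypoxia genes had a median of 0.13 (adjusted p = 0.0523 with an estimated correlation).

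Tested against each other, wild type exceeded WWAA in Lgmn (log2 6.07), Gimap7 (2.80), Hes1 (2.43, SE 0.199, adjusted p = 1.7e-05) and Notch1 (1.88), with n = 3 and 3. Fhl1 itself was higher with wild type (0.67, adjusted p = 0.000393), so the proteins also differ in transcript level. In all 141 genes were higher with wild type and 67 with WWAA, 208 together, with 183 by DESeq2 and 567 with the block (310 and 257). The count was 92, 79 and 134 without wild type replicates 1, 2 and 3, and 113 and 98 without WWAA replicates 1 and 2. Between the proteins Notch targets had a median of 0.22 (adjusted p = 0.00214 with an estimated correlation). Proliferation genes had a median of −0.11 (adjusted p = 0.0118 with an estimated correlation). Against GFP their median was 0.11 with WWAA (adjusted p = 8.53e-06; adjusted p = 0.0650 with an estimated correlation) and −0.03 with wild type (adjusted p = 0.0366; adjusted p = 0.232 with an estimated correlation).

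Genes that rose on depletion had a median of 0.06 with wild type KYOT2 (fry adjusted p = 1.22e-05), where 16 of 594 passed upward and 1 downward. Their median was −0.03 with WWAA (fry adjusted p = 0.00143) and 0.09 between wild type and WWAA (fry adjusted p = 1.75e-06). Camera passed for these genes with wild type (adjusted p = 0.000181) and between the proteins (adjusted p = 3.46e-08). With WWAA camera did not pass (adjusted p = 0.171). Genes that fell on depletion had a median of −0.0013 with wild type (adjusted p = 0.160), 0.01 with WWAA (adjusted p = 0.0416) and −0.01 between them (adjusted p = 0.305). With WWAA the fry p of the genes that fell, unadjusted, was above 0.05 when any of 6 of the 9 libraries was left out, and camera did not pass (adjusted p = 0.242). For genes that fell at least 2-fold on depletion the medians turned upward, to 0.0257 with wild type (fry adjusted p = 0.0304) and 0.0536 between wild type and WWAA (fry adjusted p = 0.0468). Camera passed for neither (adjusted p = 0.265 and 0.304). With WWAA neither set passed with the 2-fold lists (adjusted p = 0.0694 and 0.817).

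With the gamma-secretase inhibitor, the mitotic kinesin gene Kif14 fell from 172 ± 0.997 to 59.0 ± 0.224 CPM (log2 −1.54, SE 0.055, n = 2 and 2). The 2 GSI libraries differed by less than sampling noise, so the errors of this comparison may understate the spread between cultures. The mitotic kinase gene Plk1 fell by 1.05, Bub1 by 0.92 and the cyclin gene Ccnb1 by 0.91. The lysosomal protease gene Ctsl rose 5.49-fold and the glucuronosyltransferase gene Ugt1a6a 4.61-fold; Ugt1a1, Ugt1a2, Ugt1a5, Ugt1a7c, Ugt1a9 and Ugt1a10 hold nearly the same counts. Hes1 was at 2 counts against 7 with DMSO (ratio 3.12, 0.594 to 30.8), Notch1 did not pass (0.57, adjusted p = 0.249), and Rbpj rose by 0.20 (adjusted p = 0.00132; DESeq2 0.119).

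GSI raised 1066 genes and lowered 1348, 2414 of 11634, with 690 by DESeq2. Without a library 1 sample is left in its group, so no count of that fit is given. Proliferation genes had a median of −0.44, with 18 of 20 down adjusted over the list alone (adjusted p = 4.26e-24; adjusted p = 0.392 with an estimated correlation). ER stress genes had a median of 0.23 (adjusted p = 4.78e-08; adjusted p = 0.392 with an estimated correlation), with 9 of 13 up adjusted over the list alone, among them the pseudokinase gene Trib3 by 0.73. Cholesterol synthesis genes had a median of 0.15 (adjusted p = 3.98e-05; adjusted p = 0.477 with an estimated correlation) and glycolysis genes −0.08 (adjusted p = 0.000918; adjusted p = 0.492 with an estimated correlation). Interferon genes had a median of 0.24 (adjusted p = 0.0169; adjusted p = 0.392 with an estimated correlation). Notch targets did not pass (adjusted p = 0.906).

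Genes that rose on depletion had a median of 0.06 with GSI (fry adjusted p = 0.0715), with 144 of 675 passing upward and 68 downward. Those that rose at least 2-fold on depletion had a median of 0.11 (adjusted p = 0.0304). Genes that fell on depletion had a median of 0.0056 there (adjusted p = 0.155).

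Among 11309 genes tested in both experiments, 114 rose on depletion and with NICD1-ER at 24 h, against 41.4 expected (odds ratio 3.52, 2.81 to 4.395, adjusted p = 3.34e-23); they include Hes1, Lgmn and Gbp2. Another 62 rose on depletion and fell with NICD1-ER, against 29.9 expected (odds ratio 2.35), and 42 fell in both, against 17.9 expected (odds ratio 2.63). Of the genes that rose on depletion, 16 also rose with wild type KYOT2, against 4.404 expected (odds ratio 4.37, 2.34 to 7.70, adjusted p = 1.47e-05), among them Hes1, Lgmn, Notch1 and Spen. With NICD1-ER and wild type KYOT2, 29 genes rose in both, against 4.95 expected (odds ratio 8.63, 5.29 to 13.8), among them Cd28, Gzmb, Hes1, Lgmn and Tnfrsf9. Of the genes that rose on depletion, 144 rose with GSI, against 61.2 expected (odds ratio 3.001). Overlaps above expectation also joined opposite directions. With GSI, 119 genes rose that fell with NICD1-ER, against 45.0 expected (odds ratio 3.45), and 127 that rose with NICD1-ER, against 61.4 expected (odds ratio 2.502). Another 100 rose with NICD1-ER and fell with GSI, against 78.5 expected (odds ratio 1.35, adjusted p = 0.0168), and 9 fell with NICD1-ER and rose with wild type KYOT2, against 3.74 expected (odds ratio 2.60, adjusted p = 0.0204). Of the genes that fell on depletion, 39 rose with NICD1-ER, against 24.8 expected (odds ratio 1.67), and 58 rose with GSI, against 38.2 expected (odds ratio 1.64).

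RBPJ regions of the control line numbered 1752, with a median of 462 bp, and 99.03% of them overlapped ATAC-seq regions (98.45 to 99.43%). H3K4me3 regions overlapped 97.37% of them (96.51 to 98.07%) and H3K27ac regions 95.55% (94.47 to 96.47%) by at least 1 bp, where random placements gave means of 2.466 to 2.835% for these 3 lists. H3K4me1 overlapped 13.47% by at least 1 bp (11.91 to 15.16%, random mean 6.362%). With at least 50% of the region covered the share was 4.167% (random mean 4.365%) and with the midpoint 4.11% (4.358%), so the excess over random placement rests on the 1 bp rule. The mark lists name no line, and they may pool control cells and line 2-12. With BioNICD1 the list held 3735 regions, of which 31.3% overlapped the control list (29.81 to 32.81%), and 66.38% of the control regions overlapped the BioNICD1 list (64.11 to 68.59%). The matched control of BioNICD1 is Biocontrol, and no RBPJ list of Biocontrol cells was used here. Differences between the lists therefore cannot be put down to BioNICD1. The series holds the marks and ATAC-seq only in cells without BioNICD1. Of the BioNICD1 regions 92.82% overlapped H3K4me3 and 19.49% H3K4me1 (18.23 to 20.8%), or 10.28% for H3K4me1 with at least 50% of the region covered (random mean 4.454%).

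Among 47748 ATAC-seq regions, those with control RBPJ overlapped H3K4me3 in 98.78% of cases and those without in 56.31% (odds ratio 62.77, Fisher's exact test). For H3K27ac the shares were 98.14 and 58.9% (odds ratio 36.81). For H3K4me1 the shares were 50 and 67.52% (odds ratio 0.4811, Fisher's exact p = 5.01e-49). Each list is a single set of positions, so no difference between replicates enters these tests.

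**Figure D5:**
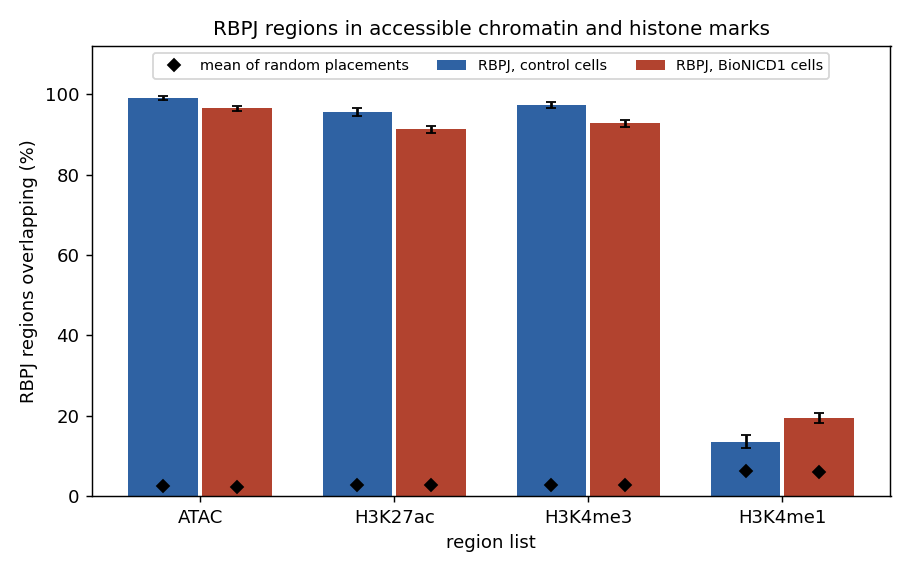
Share of RBPJ regions that overlap ATAC-seq and histone mark regions, with exact 95% intervals and the mean of random placements.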

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

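The test of construct level was chosen after the difference between control and depleted cells had been seen; the predictions of the other tests were written before they were run. Genes that were near 0 on one side of the depletion comparison, 70 that came on and 24 that went off, stood out as a pattern of switching. At the CPM of the depleted lines the 70 that came on had a median expected count of 39.9 in the control libraries. They were picked for passing with at most 3 control counts, which already requires a high expected count. The value is therefore no separate test of shallow control libraries. Origin of the edited lines rather than loss of RBPJ stays open: of 11 genes that came on and could be tested with wild type KYOT2, 0 rose there (0.0816 expected), and the Fisher exact p of 1 has no power to separate the explanations. Of the 94 genes 3 passed between lines 2-12 and 2-14, and 64 of the 79 tested with Biocontrol passed there in the same direction. The genes were picked on both lines together, so few differences between the lines follow in part from that choice. Separate edited lines of known origin, or RBPJ restored in them, would be needed to decide.

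BioNICD1 changed many genes in control cells and few in depleted cells, and less construct in depleted cells would be a technical reason. The log2 ratio of mean Notch1 CPM with BioNICD1, depleted over control, was 2.39, which argues against a lower level of construct transcript. These reads include endogenous Notch1, and protein was not measured. Without the 2 most distant depleted libraries the response still differed, for 4665 genes, of which 2514 were among the 2548 of all libraries. As far as transcript levels go, these values leave room for a response that needs RBPJ. Hes1, Il2ra, Myc and Gzmb were already raised by depletion with Biocontrol, so their smaller response may also reflect that level. The interferon, T cell activation and Notch target lists had positive medians there too, so the same holds for their differences. On the same depletion Dtx1 fell. Hey1 did not pass in the main fit, but it rose and passed with DESeq2 (2.23, adjusted p = 0.00697) and with RLE factors (adjusted p = 0.0491). The control and depleted lines may differ in more than RBPJ.

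Notch targets such as Dtx1 and Il2ra were high in ethanol NICD1-ER libraries, which could reflect a construct active without 4-OHT. Of 749 genes that rose at least 2-fold with BioNICD1, the 745 other than Notch1, Dtx1, Hes1 and Il2ra had a median log2 difference of 0.18 between ethanol and DMSO libraries, below the 0.5 set as a prediction for an active construct. Their median exceeded that of the 305 genes that fell by 0.36, and the latter had a median of −0.18. NICD1-ER active without 4-OHT and a general difference between the experiments both stay open, since the libraries come from different experiments.

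Regroupings of the libraries of a comparison, each possible one or, for the interaction, a seeded draw, were fitted to ask how often a grouping by chance gives as many genes. With KYOT2 wild type, KYOT2 WWAA, wild type against WWAA, BioNICD1 in control cells and depletion with Biocontrol, 1 of 10 splits, the real one, reached the real count, and the highest other split called 0 genes; 10 splits are too few for a p under 0.05. For BioNICD1 in depleted cells 2 of 10 splits reached 469, and the other called 2232. That split puts depleted BioNICD1 replicate 1 and depleted Biocontrol replicate 3 on the same side, which points to a structure of the samples other than the construct. For the interaction of BioNICD1 and RBPJ 2 of 100 splits reached 2548; the other called 3704 and keeps the real control groups while it puts the same 2 depleted libraries together.

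Differences between the edited lines set the following values apart, since both lines were made to lack the same gene. The lines differed in 56 genes. Tmem205 was higher in line 2-12 by 9.06 log2 units, Aifm2 by 8.91 and Plekhg3 by 8.80. Lower in line 2-12 were Lamc1 (−7.33), Sdc1 (−7.20) and Lipo1 (−6.82). Aifm2 did not pass without replicate 1 or 2 of line 2-12 (8.93, 8.84) or of line 2-14 (8.94, 8.81), and Tmem205 did not without replicate 2 of line 2-12 (8.94) or of line 2-14 (8.96). Sdc1 did not pass without replicates 1 or 2 of line 2-12 (−7.03, −7.47) or replicate 2 of line 2-14 (−7.03). Lipo1 did not pass without control replicate 1 or 2 (−6.85, −6.82), replicate 1 or 2 of line 2-12 (−6.18, −8.94) or replicate 2 of line 2-14 (−6.25). Myeloid markers had a median of 0.88 over 3 genes (camera adjusted p = 0.00127; adjusted p = 0.379 with an estimated correlation) and proliferation genes a median of −0.11 (camera adjusted p = 0.0491; adjusted p = 0.916 with an estimated correlation).

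Differences between 24 and 4 h of 4-OHT set the next values apart, 1584 genes in all. Prf1 was higher at 24 h by 7.55, Cdh15 by 5.41, Mgst1 by 4.27, Nrarp by 2.78 and Hey1 by 1.94. Dtx1 (0.49), Notch1 (0.55) and Il2ra (0.16) were higher, and Fosb (−2.12), Trat1 (−1.72), Slc15a1 (−1.46) and Myc (−0.18) lower. With DESeq2 and with the block neither Il2ra (adjusted p = 0.337 and 0.0862) nor Myc (0.410 and 0.0637) passed. Il2ra did not pass without replicates 1 and 2 at 4 h (0.13) or replicate 2 or 3 at 24 h (0.18, 0.13). Myc did not pass without replicates 1 and 2 at 4 h (−0.17), replicate 2 or 3 at 24 h (−0.12, −0.23), or replicates 1 and 2 or replicate 3 at 8 h (−0.17, −0.17). The median of Notch targets was 0.30 (adjusted p = 0.0401 with an estimated correlation, and 0.0551 without Notch1). The other lists did not pass with an estimated correlation. Their medians were 0.15 for T cell activation (adjusted p = 0.0551 with an estimated correlation), 0.51 for myeloid markers (0.0783), −0.18 for the MYC list (0.0783), 0.13 for glycolysis (0.180), 0.37 for interferon genes (0.0551) and 0.10 for cholesterol synthesis (0.420).

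Differences between KYOT2 wild type and WWAA set apart 208 genes. Lgmn was higher with wild type by 6.07, Gimap7 by 2.80, Gimap8 by 2.70, Hes1 by 2.43, Notch1 by 1.88, Fhl1 by 0.67 and Rbpj by 0.30. Rmi2 (−0.58), Chek1 (−0.47) and Lztfl1 (−0.43) were lower. Rbpj did not pass without replicate 1, 2 or 3 of wild type (0.31, 0.32, 0.27) or replicate 1 or 2 of WWAA (0.27, 0.25). Chek1 did not pass without replicate 3 of wild type (−0.38) or replicate 2 of WWAA (−0.46). Rmi2 did not pass with DESeq2 (adjusted p = 0.0710) or without replicate 1, 2 or 3 of wild type (−0.61, −0.49, −0.64) or of WWAA (−0.56, −0.62, −0.57). Medians were 0.22 for Notch targets, 0.0416 for T cell identity, 0.28 for T cell activation, −0.11 for proliferation and −0.11 for cholesterol synthesis. RBPJ cofactors, which hold Fhl1, had a median of 0.0481 and, without Fhl1, of 0.0475 (adjusted p = 0.0511 with an estimated correlation). Lists that did not pass with an estimated correlation had medians of 0.0529 for Notch machinery (adjusted p = 0.0511 with an estimated correlation), −0.0743 for the MYC list (0.170), −0.0893 for glycolysis (0.113), 0.34 for interferon genes (0.0550) and 0.11 for p53 targets (0.0511).

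Differences between the BioNICD1 response in depleted and in control cells set apart 2548 genes. The response was higher in depleted cells for Lonrf3 (4.50), Xk (3.55), Ccr9 (3.13), Odf2 (2.86), Stbd1 (2.84), Bcor (2.70), Nrp1 (2.62), Map9 (2.496) and Rbpj (0.42). It was lower for Cdh15 (−13.79), Prf1 (−12.40), Pdgfrb (−10.03), Il2ra (−9.57), Gcnt2 (−9.49), Tgtp1 (−9.39) and Epas1 (−9.22), values that depend on the prior count where a group is near 0. It was lower for Hey1 (−7.97), Dtx1 (−7.43), Hes1 (−3.10), Myc (−0.55), Gzmb (−7.46) and Tnfrsf9 (−2.56). It was lower for Adm (−1.89), Egln3 (−1.05), Gapdh (−1.07) and Pfkl (−0.82). It was lower for Gbp2 (−6.93), Zbp1 (−3.49) and Isg15 (−2.89). Median differences were −1.60 for Notch targets (−2.48 without Notch1), −0.82 for T cell activation, −0.36 for glycolysis and −3.19 for interferon genes. Without replicate 2 of depleted cells with Biocontrol, Cdh15 (−11.16), Pdgfrb (−8.22), Lonrf3 (4.45) and Myc (−0.46) did not pass. Lonrf3 did not pass without replicate 1 or 2 of control cells with Biocontrol (4.09, 4.55) or replicate 2 or 3 of control cells with BioNICD1 (4.48, 4.49). Myc did not pass without replicate 2 of control cells with Biocontrol (−0.53) or with BioNICD1 (−0.49) or replicate 1 of depleted cells with Biocontrol (−0.55). Rbpj did not pass without replicate 1, 2 or 3 of control cells with Biocontrol (0.42, 0.45, 0.39), replicate 1 or 2 of control cells with BioNICD1 (0.41, 0.41), replicate 1 or 2 of depleted cells with Biocontrol (0.45, 0.42) or replicate 3 of depleted cells with BioNICD1 (0.33).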

How the results depend on the processing

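Limits come from depth and from groups of 2 or 3 samples: a control library of 2377028 counts sets 3 counts at 1.26 CPM, and simulated 1.5-fold changes were called in 12% of genes in the depletion design. Of 328 values under alternatives other than leaving out a library, 240 kept their direction, side of the threshold and size, and of 257 values without a library 185 did. Of 1229 values of named genes under alternatives, 1175 kept direction and side of the threshold. Where no cause is given, the cause was not tested. RLE factors moved no count of calls by over 1.5 times. The test of RBPJ regions with stronger scores was not run, because every score is 0, and RBPJ-bound genes and expression, with windows of 1 kb and 50 kb, was not run, because no mm9 annotation was used here.

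Without the low-count filter, which tests more genes and made 28.2% false calls in simulated depletion data, counts of changed genes were 2671 for both edited lines, 2126 for line 2-12, 1870 for line 2-14 and 302 between the lines. They were 262 for KYOT2 wild type, 66 for WWAA and 395 between them. The median of Notch targets was 0.0579 on depletion with Biocontrol (adjusted p = 0.157) and −0.16 with BioNICD1 in depleted cells (0.881), and that of T cell identity on depletion with Biocontrol was 0.0011 (0.237).

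With the replicate number as a block, counts were 4260 for both edited lines, 3672 for line 2-12, 3243 for line 2-14 and 282 between the lines. The labels of the other experiments name no shared culture, day or batch. Libraries correlated best with their own number in 6 of 10 cases with NICD1-ER, 8 of 9 with KYOT2, 4 of 4 with GSI and 7 of 12 with BioNICD1. With GSI every correlation between the groups has the same size, 0.0268, and only the sign differs, so pairing cannot be judged there. The block gave 320 genes for KYOT2 wild type, 67 for WWAA and 567 between them, and 664, 1064, 1662 and 1313 for NICD1-ER at 4, 8 and 24 h and for 24 against 4 h. It gave 2535 for GSI, and 3813, 440, 2633 and 4816 for BioNICD1 in control cells, in depleted cells, the interaction and depletion with Biocontrol. Kept apart with the block, an alternative added after the data were seen, NICD1-ER at 4 h gave 1223. With the block the median of interferon genes with GSI was 0.24 (adjusted p = 0.0530), of Notch targets with BioNICD1 in depleted cells −0.0639 (0.425) and of T cell identity on depletion with Biocontrol −0.0494 (0.244). Ptcra between 24 and 4 h turned to −0.0530 with the block. In the depletion experiment the block also brought Ptcra (−1.37, adjusted p = 0.0375), Slc2a1, Adm, Pgam1, Eno1, Asns, Hspa5, Phgdh and Atf4 under the threshold for both lines and Hey1 (3.26, adjusted p = 0.0347) in line 2-14, and it changed the call of no list there.

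In 1 fit over all libraries, which shares the error between experiments, counts were 4377 for both edited lines, 3923, 3344 and 411 for line 2-12, line 2-14 and their difference, and 94, 232, 453 and 285 for NICD1-ER at 4, 8 and 24 h and 24 against 4 h. They were 73 between KYOT2 wild type and WWAA, 451 for GSI, 1627 for BioNICD1 in depleted cells and 4747 for the interaction. DESeq2 called 118 genes between the lines, 229, 429, 617 and 481 with NICD1-ER at 4, 8 and 24 h and 24 against 4 h, 22 with WWAA, 690 with GSI and 766 with BioNICD1 in depleted cells. With the near-identical pairs at 24 h of 4-OHT and of GSI summed, 1 sample is left in the treated group. The spread then comes from other groups only, so no count of that fit is given. Without the 2 most distant depleted libraries, an alternative added later, BioNICD1 changed 5882 genes in control cells and 1285 in depleted cells, and 4665 differed.

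With the genes changed at least 2-fold, the median of genes that fell on depletion turned to 0.0257 with KYOT2 wild type (fry adjusted p = 0.0304) and to 0.0536 between wild type and WWAA (0.0468). Camera passed for neither. With WWAA the medians were −0.0322 for genes that rose on depletion (adjusted p = 0.0694) and 0.0164 for those that fell (0.817). With GSI the median of those that rose was 0.11 (0.0304). The median of genes that fell with NICD1-ER turned to −0.07 with BioNICD1 in control cells (fry 0.0046, camera 0.332) and to 0.03 for the interaction (fry 0.385).

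With an estimated correlation the medians stay as they are and these lists no longer passed. On depletion they were Notch targets (1.11), glycolysis (−0.51), interferon (2.37), ER stress (−0.50) and cholesterol synthesis (−0.45). With NICD1-ER at 24 h they were T cell activation (0.32), the MYC list (−0.13) and interferon (0.37). With KYOT2 wild type they were proliferation (−0.0317), glycolysis (0.0492) and cholesterol synthesis (−0.0419). With GSI they were proliferation (−0.44), glycolysis (−0.0788), interferon (0.24), ER stress (0.23) and cholesterol synthesis (0.15). With BioNICD1 in control cells they were proliferation (0.29), glycolysis (0.40) and ER stress (−0.35), and in depleted cells the MYC list (0.28) and ER stress (−0.32). On depletion with Biocontrol they were T cell identity (−0.0493) and interferon (0.78). Without the expressed gene and at the preset correlation, RBPJ cofactors with KYOT2 wild type had a median of 0.0030 (adjusted p = 0.112). Notch targets with BioNICD1 in depleted cells then had −0.14 with the test turned downward (adjusted p = 0.824).

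Leaving out 1 library gave 379 to 2511 genes for both edited lines, 259 to 1914 for line 2-12, 200 to 1303 for line 2-14 and 3 to 54 between the lines. With NICD1-ER it gave 434 to 729 at 4 h (465 without replicates 1 and 2 at 4 h), 614 to 1434 at 8 h (774 without ethanol replicate 3 and 1426 without replicate 3 at 4 h), 746 to 1420 at 24 h and 702 to 1774 for 24 against 4 h (1024 without replicates 1 and 2 at 4 h). With KYOT2 it gave 50 to 239 for wild type, 6 to 18 for WWAA and 79 to 239 between them, and with GSI 1436 to 2276. With BioNICD1 it gave 2701 to 4663 in control cells, 165 to 1224 in depleted cells and 1614 to 4361 for the interaction, and 3666 to 5520 for depletion with Biocontrol. The median of genes that fell on depletion ran from −0.0084 to 0.0080 with KYOT2 wild type, 0.0070 to 0.0229 with WWAA and −0.0104 to 0.0106 with GSI. Myc ran from −0.0148 to 0.10 on depletion, −0.0442 to 0.19 in line 2-12, −0.0741 to 0.10 in line 2-14, −0.0589 to 0.18 between the lines and −0.0074 to 0.0475 with KYOT2 wild type. Hes1 ran from −0.74 to 1.04 between the lines. Ptcra ran from −0.18 to 0.25 (−0.0185 without ethanol replicate 3) and −0.21 to 1.12 with NICD1-ER at 8 and 24 h, −0.54 to 0.78 for 24 against 4 h, −0.26 to 0.0062 with KYOT2 wild type and −0.15 to 0.0352 with GSI. Notch1 ran from −0.13 to 0.21 with WWAA, and with BioNICD1 in depleted cells Hey1 ran from −0.34 to 0.87 and Dtx1 from −0.55 to 0.0293.

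Where at least 50% of a region had to be covered, or its midpoint, H3K27ac held 76.48 or 71.8% of control RBPJ regions and 74.91 or 72.96% of BioNICD1 regions. H3K4me3 held 86.24 or 81.96% and 81.93 or 80.56%, and H3K4me1 held 4.167 or 4.11% and 10.28 or 10.09%. The BioNICD1 list held 56.39 or 59.59% of the control regions. These criteria demand more overlap, yet the ATAC-seq shares hardly changed. They were 98.74 or 98.8% of control RBPJ regions and 96.12% by either rule for BioNICD1 regions. Why the other shares fell more was not tested.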

Other observations

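No test was chosen for the values that follow. With GSI, the hypoxia-linked genes Adm (log2 −0.59) and Ankrd37 (−0.58) fell, and the lanosterol synthase gene Lss rose by 0.29 (edgeR, n = 2 and 2). With BioNICD1 in control cells the replication gene Mcm7 rose by 1.19 and the cyclin gene Ccne1 by 1.49, and in depleted cells Mcm7 rose by 0.56 (edgeR, n = 3 and 3).

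Of the B cell, myeloid, erythroid and fibroblast markers the highest in the NICD1-ER libraries were Cd22 at 138, Cd68 at 28.3, Alas2 at 4.71 and Pdgfrb at 2.40 CPM. In the BioNICD1 libraries they included Cd22 at 52.2, Cd68 at 16.6 and Pdgfrb at 15.3 CPM. In the GSI libraries Cd68 was at 70.9 and Hba-a1 at 6.62 CPM, and in the KYOT2 libraries Cd68 was at 14.8 and Fcer2a at 0.350 CPM. These values are means over all libraries of an experiment and hide differences between its groups. Cd22 passed upward on depletion and with NICD1-ER at 24 h, and Pdgfrb responded less to BioNICD1 in depleted than in control cells. Neither level by itself points to other cell types.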
